A study of Oryza sativa with 12 samples.

How the data were processed

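Small RNA libraries were made from total RNA of shoots of rice cultivar Nipponbare, grown with 12 h light at 32 °C and dark at 28 °C, and sequenced in single reads on a HiSeq2500. Per the labels, RNA was taken with TRIzol, small RNA was excised from a gel and libraries were built with a New England Biolabs kit. The study covers 4 genotypes (WT, tas3a1, tas3b1 and tas3c1) with 3 replicates each. The deposited values are counts, the number of reads of each distinct adapter-free sequence in a library, with no normalization. The tools used for trimming and collapsing reads are not given in the sources used here. The labels name the genome build TAIR10, which belongs to Arabidopsis, and the count tables hold no alignments, so that build played no part in what follows.

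Reads of 18 to 26 nt without an undetermined base were kept, and their number in each library was the library size (5399077 to 10131139). Identical reads may be copies of 1 molecule, so counting floors cover counting error only. Libraries of 1 group were checked for duplication and none was a copy of another (Pearson r of log2 CPM between 0.912 and 0.949 across sequences). A table of 35276 sequences with at least 2 CPM in at least 3 libraries was tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, then glmQLFit and glmQLFTest on all 12 libraries together, contrast mutant minus WT, Benjamini-Hochberg adjusted p under 0.05). The biological coefficient of variation of that table was 0.165. The 5 fragments called TAS3-like here (21-nt reads that match exactly on either strand) were appended to it. For the C fragments, chosen because they were low in tas3c1, that is a name only. A second table held 28 microRNA families with at least 30 reads, each the sum of exact mature sequences (75 sequences in 32 families were listed, from general knowledge of conserved and grass microRNAs), and tasiARF, with the TMM factors of the sequence table. Families miR395, miR530, miR2118 and miR2275 had too few reads. Shares of read lengths and of reads in register were compared with two-sided exact permutation tests.

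The groups, the tests, the microRNA lists and the alternative settings were fixed before the data were examined, as was the rule for what the text names. It names tasiARF and miR390, the TAS3-like fragments, families past the threshold, the most abundant families of each list, and up to 10 sequences per comparison and direction with the largest fold change among called sequences at 2 CPM or more in the higher group whose libraries do not overlap with WT. Of these sequences a selection is printed. Sequences that match Cas9 are counted and not printed. The plan had TAS3 loci found in a genome. With no rice genome at hand, fragments were instead extended from overlapping reads in windows of 14 nt, and these were chosen after the data had been seen. The register of A 3′ and B was counted from the 3′ miR390 site in steps of 21 nt, with antisense reads shifted by the 3′ overhang, and that of A 5′ and C chain was the commonest one in WT.

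Cas9 and hygromycin phosphotransferase were searched for as peptides of 6 amino acids in all frames of reads of 20 to 24 nt, with the same protein sequences read backwards as the background. Overlaps between mutants were set against the product of list sizes over the number of sequences, and against 10 simulated data sets in which no group differed and the WT libraries were shared. The tests were tested on simulated data with 100 sequences changed at each fold: with 2-fold changes 41, 37 and 36 of 100 were recovered for tas3a1, tas3b1 and tas3c1, and with 4-fold changes 90, 85 and 91, with 7, 13 and 7 unchanged sequences called.

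Alternatives were DESeq2 1.42.0 with its size factors and the local dispersion trend, no TMM, only the 6 libraries of a comparison, the replicate number as a block, each replicate left out, a minimum of 0.5 CPM, fragment reads of 20 to 24 nt, tasiARF reads of 20 to 22 nt, microRNA reads that hold nucleotides 3 to 18, families with 1 read or more, and distinct sequences in place of reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Small RNA loci, reads at several genome places, genome-matched denominators, siRNAs on the auxin response factor genes and shares of organelle, ribosomal and transfer RNA were planned and not run, because each needs a rice genome. The control condition for every comparison was the WT group, measured in the same way.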

Results

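Small RNAs were sequenced from 1-week-old shoots of the rice cultivar Nipponbare. The 12 libraries formed 4 groups of 3 replicates: the wild type (WT) and the mutants tas3a1, tas3b1 and tas3c1. TAS3 genes give rise to noncoding transcripts that microRNA miR390 directs into 21-nt phased small interfering RNAs (siRNAs), among them tasiARF, which targets mRNAs of auxin response factors. The study's title concerns siRNAs from TAS3 and mRNA cleavage in rice, and each mutant was compared with WT for the small RNAs that changed. Libraries held 9135134 to 17668650 reads, of which 5399077 (WT replicate 3) to 10131139 (WT replicate 1) were 18 to 26 nt long. Levels are counts per 1000000 reads of 18 to 26 nt (CPM), as mean ± SD with n = 3. Counts of 0 are set against a floor of 3 reads over the 3 libraries of a group, and such floors cover counting error only. Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 fold changes are mutant over WT ± SE. Unless an alternative is named, these tests and log2 fold changes include TMM scaling. CPM values do not, nor do the folds and percents of WT formed from them, so they can differ from the log2 fold changes. The labels do not say whether replicates were separate plants or cultures, so each p value measures only the spread between these samples.

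All 4 groups had the 24-nt peak typical of plant heterochromatic siRNAs and a smaller 21-nt class that holds most microRNAs and phased siRNAs. The 24-nt share was 30.9% ± 0.883 in WT, 28.9% ± 0.861 in tas3a1, 29.0% ± 0.571 in tas3b1 and 27.1% ± 1.87 in tas3c1. In each mutant all 3 libraries lay below the 3 WT libraries, and each difference had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The 19-nt share was 7.04% ± 0.267 in WT, 7.80% ± 0.336 in tas3a1, 7.71% ± 0.205 in tas3b1 and 7.73% ± 0.405 in tas3c1. All libraries of each mutant lay above WT for it. Whether RNA quality differed between the groups was not tested. The 21-nt share was 11.6% ± 0.278 in WT, 11.4% ± 0.107 in tas3a1 and 11.4% ± 0.103 in tas3b1, differences of -0.171 and -0.204 percentage points with an exact permutation p of 0.4 each. In tas3c1 it was 13.4% ± 0.410, or 1.80 points above WT (exact permutation p = 0.1). Without reads that encode peptides of Cas9, the nuclease used for genome editing, a setting chosen after the data had been seen, the 21-nt share in tas3c1 was 12.1% ± 0.0622, a difference of 0.534 points, and the 24-nt share was 28.0% ± 1.71. These Cas9 reads of 20 to 24 nt stood at 30706 ± 8932 CPM in tas3c1 and 262 ± 58.6 CPM in WT, where the same protein sequence read backwards gave 206 ± 7.14 and 195 ± 14.3 CPM.

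**Figure D1:**
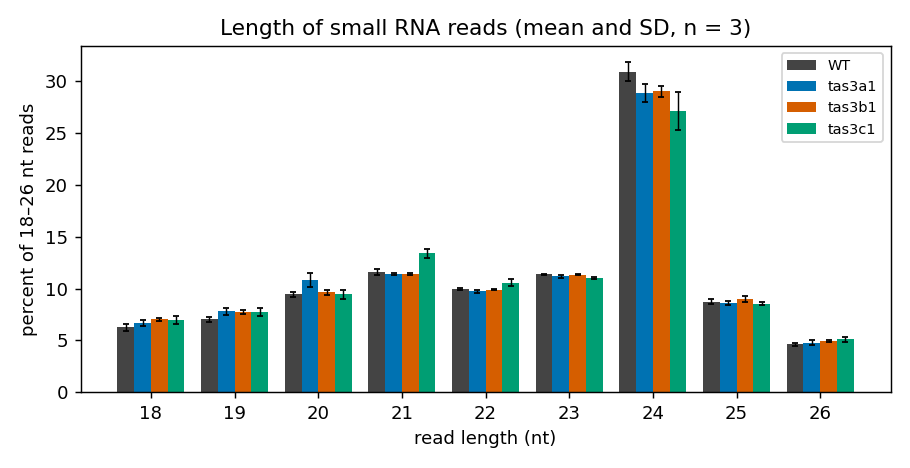
Share of reads at each length from 18 to 26 nt (percent of all reads of 18 to 26 nt) in the 4 groups, as means with SD of 3 libraries. The 24-nt share is 30.9% in WT and 27.1% in tas3c1, and the 21-nt share is 11.6% in WT and 13.4% in tas3c1.

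No rice genome was used, so 5 fragments, called TAS3-like here, were put together by hand from overlapping reads after the data had been seen. Positions are counted from 1 at the 5′ end of each fragment. Fragments A 5′ (159 nt) and B (238 nt) were extended from reads that hold the tasiARF core sequence, and A 3′ (57 nt) from reads at a miR390 site. C chain (84 nt) and C target (26 nt) were chosen because their reads were low in tas3c1, so their decrease there is not independent evidence of a TAS3 gene. Neither holds the tasiARF core, and miR390 sites are given for the A and B fragments only. For the C fragments TAS3-like is therefore a name and not a finding. Each letter follows the mutant in which the fragment was lowest, and whether A 5′ and A 3′ belong to 1 transcript was not determined. Some joins are thin: 4 of 71 windows of 14 nt in C chain, 2 of 146 in A 5′ and 1 of 225 in B had no WT read. The lowest window of C chain had 1 read over all libraries. Registers assume that these joins hold. The site in A 3′ differs from the miR390 complement at 4 of 21 positions, the A 5′ site at 5 of 21 and the 5′ end of B at 4 of 19. The 21-nt reads of WT stood at 136 ± 11.0 CPM for A 5′, 54.3 ± 8.34 for A 3′, 581 ± 47.5 for B, 71.7 ± 4.57 for C chain and 3.75 ± 0.768 for C target.

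**Figure D2:**
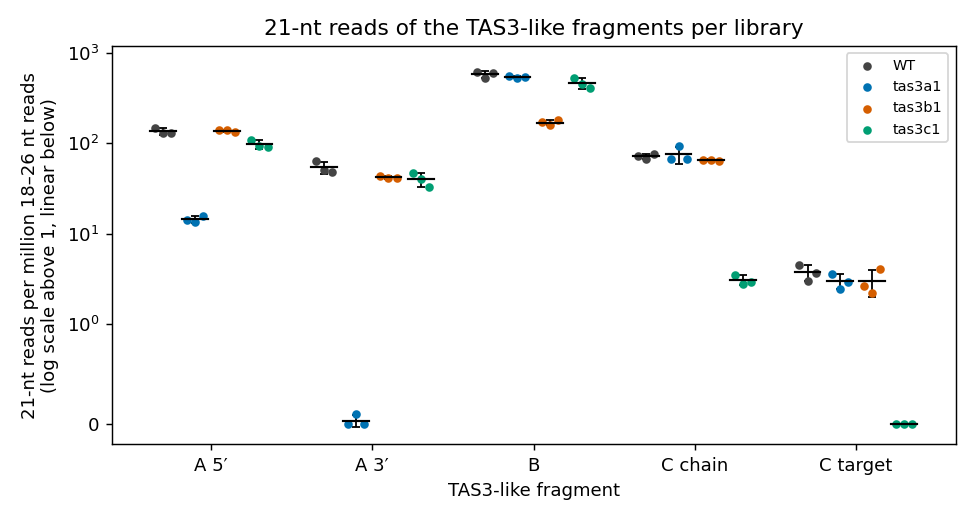
21-nt reads (CPM, log axis above 1 and linear below) of the 5 fragments in each of the 12 libraries, with group means and SD. The fragments are labelled TAS3-like, which for the C fragments is a name only. The A fragments are lowest in tas3a1 (14.4 CPM for A 5′), B in tas3b1 (170 CPM) and the C fragments in tas3c1 (3.07 CPM for C chain).

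In tas3a1, siRNAs of both A fragments fell in all 3 libraries. The 21-nt reads of A 5′ stood at 14.4 ± 1.19 CPM, 9.42-fold below WT (log2 fold change -3.25 ± 0.16, adjusted p = 4.00e-15). A 3′ was left with 1 read in the 3 libraries against 54.3 ± 8.34 CPM in WT (adjusted p = 2.72e-18). The siRNAs in the 21-nt register that dominates A 5′ in WT stood at 1.01% of their WT level and those outside it at 48.3%. B, C chain and C target did not pass the test in tas3a1, with log2 fold changes of -0.11, 0.08 and -0.35 (adjusted p = 0.899, 0.950 and 0.815).

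The siRNAs with the highest WT levels in the A fragments were nearly absent from tas3a1. TGAAGAAGGATGTGGACGGTG, antisense at positions 32 to 52 of A 5′, stood at 45.7 ± 8.53 CPM in WT and 0.597 ± 0.183 in tas3a1. CATCGTTGTGTTGTTTTTCTT, sense at 139 to 159, stood at 46.4 ± 2.30 and 0.389 ± 0.0286 CPM. AGAACTAGGAGAAAGATGGGA of A 3′ stood at 28.1 ± 3.82 CPM in WT and had no read in tas3a1, at least 264-fold lower. In the A 5′ register, 79.7% ± 2.30 of the WT reads and 7.57% ± 0.758 of the tas3a1 reads started (exact permutation p = 0.1). That register was chosen as the commonest in WT.

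tasiARF, counted as 21-nt reads that start with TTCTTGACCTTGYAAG (Y is C or T), fell from 9.74 ± 0.646 CPM in WT to 5.70 ± 1.53 in tas3a1, with all 3 libraries below WT (log2 fold change -0.79 ± 0.21, adjusted p = 0.00139). Reads of 20 to 22 nt that hold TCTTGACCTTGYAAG fell from 34.1 ± 0.660 to 9.60 ± 1.87 CPM (-1.85 ± 0.16, adjusted p = 1.95e-22). The commonest of them, TCTTGACCTTGTAAGACCCA of A 5′, stood at 9.77 ± 1.51 CPM in WT and 0.175 ± 0.113 in tas3a1. TTCTTGACCTTGCAAGACTTT of B stood at 4.65 ± 1.07 and 3.49 ± 1.36 CPM. miR390 stood at 54.5 ± 3.12 CPM in WT and 46.3 ± 6.28 in tas3a1 and did not pass the test (-0.25, adjusted p = 0.190). Without tas3a1 replicate 3 the tasiARF change was -0.59 with an adjusted p of 0.0640.

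Of 28 microRNA families tested, 7 fell in tas3a1 and none rose, with adjustment over the list alone (none rose at an unadjusted p of 0.05 or in DESeq2 either). In the stress and nutrient list 3 of 7 fell: miR528, a grass family (-0.76 ± 0.14, from 860 ± 225 to 510 ± 62.7 CPM), miR397, which targets laccases (-0.93 ± 0.18), and miR827, tied to phosphate (-0.55 ± 0.16). In the auxin list 2 of 4 fell, miR167, which targets auxin response factors (-0.44 ± 0.13, from 910 ± 96.5 to 676 ± 39.4 CPM), and miR164, which targets NAC genes (-0.39 ± 0.15). In the development list 2 of 10 fell, miR171 (-0.49 ± 0.16) and miR319, which targets TCP genes (-0.39 ± 0.13), while miR396 stood at 8548 ± 626 CPM in WT and 8035 ± 914 in tas3a1. None of the 2 machinery families (miR162 and miR168) and none of the 4 monocot or grass families (miR444, miR820, miR1425 and miR1432) passed, adjusted or not. All tas3a1 libraries lay below all WT libraries for 10 of the 28 families and above them for none, where chance gives 10% for both directions together. Of 41 mature sequences in the table of all sequences, 3 fell in tas3a1 with adjustment over all sequences and 4 were called when adjusted over the list alone. Calls ended without single libraries: miR164 without WT replicates 1 or 2 or tas3a1 replicates 2 or 3 (adjusted p = 0.170, 0.0654, 0.113 and 0.130), miR171 without WT replicate 2 or tas3a1 replicates 2 or 3 (0.0939, 0.0800 and 0.0640), miR319 without WT replicate 3 or tas3a1 replicate 3 (0.136 and 0.171) and miR827 without tas3a1 replicate 2 (0.0739). Without tas3a1 replicate 3, 4 families were called. With reads that hold nucleotides 3 to 18 of a mature sequence the calls on miR167 (-0.27, adjusted p = 0.110), miR164 (-0.31, 0.0832) and miR319 (-0.32, 0.0632) were lost.

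**Figure D3:**
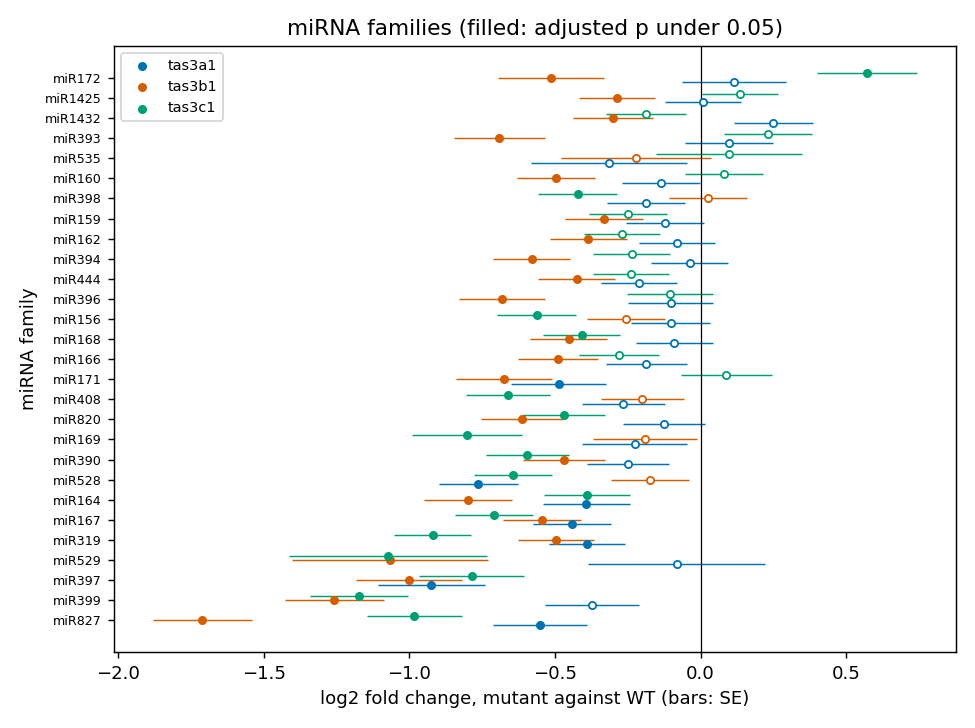
Log2 fold change (mutant over WT, with SE) of the 28 microRNA families in the 3 mutants, from edgeR's quasi-likelihood fit to all 12 libraries. Filled symbols passed an adjusted p of 0.05, with 7 families in tas3a1, 22 in tas3b1 and 16 in tas3c1, and miR172 in tas3c1 is the called family above 0.

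Among 35276 single sequences, 131 rose and 84 fell in tas3a1. Of the 10 named decreases, 7 lay in the A fragments and all 10 had no read in tas3a1. Sequences of 24 nt outside the fragments were also named: GATGGATCTGTACTATATGAGAGC stood at 25.1 CPM in WT, 36.0 in tas3b1 and 1.83 in tas3c1 with no read in tas3a1, at least 236-fold lower. Of the 10 named increases 9 were 24 nt long, such as AGAAGTGTCAAATCTACTGAATGT with 1.48 CPM in WT and 19.0 in tas3a1 (3.76 ± 0.32, adjusted p = 1.25e-09). The called 24-nt sequences numbered 41 higher and 35 lower. Without WT replicate 1 the count was 104 in place of 215 (46 higher and 58 lower), without WT replicate 2 it was 139 (68 higher and 71 lower), and the increase of ATTAAACTCGGCTCAATCTGAAA lost its call in DESeq2 (4.03, adjusted p = 0.0941) and without WT replicate 1, WT replicate 2 or tas3a1 replicate 1 (adjusted p = 0.128, 0.0985 and 0.179).

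In tas3b1, siRNAs of fragment B fell and the phased pattern of B was lost. The 21-nt reads of B stood at 170 ± 10.03 CPM, 3.41-fold below WT, in all 3 libraries (log2 fold change -1.97 ± 0.16, adjusted p = 2.05e-10). Reads in the register of the 3′ miR390 site stood at 3.50% of their WT level, while reads outside it stood at 120%. A 5′ (-0.18, adjusted p = 0.550), C chain (-0.34, adjusted p = 0.262) and C target (-0.52, adjusted p = 0.340) did not pass. A 3′ was lower by a small margin, at 42.1 ± 1.47 CPM (-0.57 ± 0.17, adjusted p = 0.0499). That call was lost in each of the 6 fits without a replicate, with adjusted p of 0.192, 0.0907 and 0.0860 without WT replicates 1, 2 and 3 and of 0.0977, 0.191 and 0.0864 without tas3b1 replicates 1, 2 and 3, and without TMM scaling (0.198).

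The in-register siRNAs of B with the highest WT levels were scarce in tas3b1. CGAAACGAAAAGAATGCCTCT, antisense at positions 69 to 89, stood at 145 ± 20.8 CPM in WT and 9.001 ± 0.949 in tas3b1. TGGGAGGAGTGATAGACGCGA, antisense at 195 to 215, stood at 112 ± 10.7 CPM in WT with 1 read in tas3b1. TCATCGAAAAACACTCTTCTT, sense at 134 to 154, stood at 92.4 ± 8.83 and 2.80 ± 0.626 CPM. The out-of-register siRNA AGCATCCGAGAATAGAACGAG, antisense at 39 to 59, stood at 2.02 ± 0.235 CPM in WT and 22.4 ± 1.21 in tas3b1. In-register reads were 77.9% ± 1.18 of the B reads in WT and 9.24% ± 0.418 in tas3b1 (exact permutation p = 0.1). Up to position 197 the 21-nt reads of B stood at 443 CPM in WT and 170 in tas3b1, and reads that cross or lie past that position stood at 138 and 0.145 CPM.

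**Figure D4:**
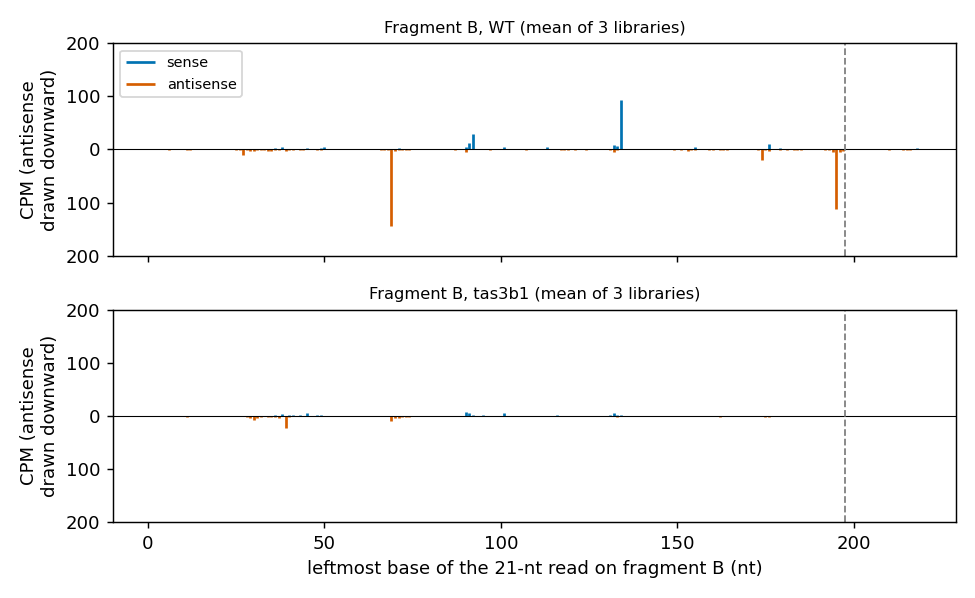
21-nt reads of fragment B by their leftmost base (CPM, group means of 3 libraries, antisense reads drawn downward) in WT and tas3b1, with a dashed line after position 197, the last base before the tas3b1 junction. The WT peaks at 69 and 195 (antisense) and 134 (sense) are small or absent in tas3b1, and reads that cross or lie past the line stand at 0.145 CPM in tas3b1 and 138 in WT.

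tasiARF fell in tas3b1 in all 3 libraries, to 3.71 ± 0.216 CPM (-1.59 ± 0.22, adjusted p = 4.77e-11). TTCTTGACCTTGCAAGACTTT, at positions 113 to 133 of B, stood at 4.65 ± 1.07 CPM in WT and 0.256 ± 0.188 in tas3b1, whereas TTCTTGACCTTGTAAGACCCA of A 5′ stood at 3.69 ± 0.240 and 2.69 ± 0.325 CPM. The 20 to 22 nt reads stood at 24.1 ± 0.286 CPM (-0.70 ± 0.15, adjusted p = 2.93e-05). miR390 fell to 45.1 ± 3.58 CPM (-0.47 ± 0.14, adjusted p = 0.00188), a call that was lost without TMM scaling (-0.27, adjusted p = 0.0884).

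In tas3b1 22 of the 28 microRNA families fell, with a median log2 fold change of -0.49, and none rose, at an unadjusted p of 0.05 and in DESeq2 included. All 4 auxin families fell: miR164 (-0.80 ± 0.15), miR393, which targets auxin receptors (-0.69 ± 0.16), miR167 (-0.55 ± 0.13, to 715 ± 26.9 CPM) and miR160 (-0.50 ± 0.13). In the development list 8 of 10 fell: miR529 (-1.07), miR396, which targets growth-regulating factors (-0.68 ± 0.15, from 8548 ± 626 to 6102 ± 686 CPM), miR171 (-0.67), miR394 (-0.58), miR172 (-0.51), miR319 (-0.50), miR166 (-0.49, from 1715 ± 445 to 1393 ± 77.6 CPM) and miR159 (-0.33), and miR156 and miR535 did not pass. In the stress and nutrient list 3 of 7 fell: miR827 (-1.71 ± 0.17, from 25.1 ± 0.897 to 8.69 ± 1.71 CPM) and miR399 (-1.26 ± 0.17, from 21.1 ± 1.53 to 10.2 ± 1.29 CPM), which belong to the phosphate response, and miR397 (-1.001 ± 0.18). miR408, which targets copper proteins, stood at 4562 ± 270 CPM against 4561 ± 137 in WT. Both machinery families fell, miR168 (-0.45), which targets AGO1, and miR162 (-0.39), which targets DCL1, as did miR820 (-0.61), miR444 (-0.43), miR1432 (-0.30) and miR1425 (-0.29), the 4 monocot or grass families. All tas3b1 libraries lay below all WT libraries for 14 families and above them for none, where chance gives 10% for both directions together, and of the mature sequences 17 fell over all sequences and 29 were called when adjusted over the list alone.

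These family calls in tas3b1 depend on scaling, on some libraries and on the model. Leaving out TMM moved the median of all sequences by 0.19 in tas3b1, 0.18 in tas3c1 and 0.00 in tas3a1 (log2), and 12 families were then called in tas3b1, all lower. Besides miR390, the calls on both machinery families, miR168 (-0.25, adjusted p = 0.0679) and miR162 (-0.18, 0.140), on 3 of the 4 monocot or grass families, miR444 (0.0948), miR1425 and miR1432 (0.513 each), on miR160 (0.0742) and on miR159, miR166 and miR172 (0.466, 0.0884 and 0.210) were then lost. Calls also ended without single libraries: miR159 and miR166 without WT replicate 1 (adjusted p = 0.402 and 0.0533), miR172 without WT replicates 1 or 2 or tas3b1 replicate 2 (0.0533, 0.0562 and 0.219), miR1425 without WT replicates 2 or 3 or tas3b1 replicates 1 or 2 (0.203, 0.0558, 0.0991 and 0.182) and miR1432 without WT replicates 1 or 2 or tas3b1 replicate 2 (0.1003, 0.0775 and 0.307). The call on miR172 was also lost in DESeq2 (-0.49, adjusted p = 0.131), and with only the 6 libraries of WT and tas3b1 so were those on miR172 (0.0566), miR1425 (0.0566) and miR1432 (0.0589).

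Single sequences in tas3b1 numbered 686 higher and 862 lower. Of the 10 named decreases 6 lay in B, such as TGGGAGGAGTGATAGACGCGAG (5.28 CPM in WT, no read in tas3b1, at least 49.97-fold lower). The 10 named increases held 5 sequences of 24 nt and 5 of 21 or 22 nt with no read in the other groups, the highest of which was CACAAGCTCACGAGAGGACGAG with 9.55 CPM in tas3b1, at least 80.2-fold higher than WT. Its reverse complement is B up to position 197 followed by the last 7 bases of the miR390 complement, so it is a read of the tas3b1 junction. The rest of these 5 overlap it or each other across or past that break. The 5 are therefore not independent of the change in B, whose counts above leave such reads out. Of the 24-nt sequences 109 rose and 183 fell, and without TMM 248 rose and 67 fell. Without TMM 1869 rose and 444 fell, or 80.8% higher in place of 44.3%, so the split by direction rests on the scaling. Without WT replicates 1, 2 or 3 or tas3b1 replicate 2 the count of called sequences was 1009, 808, 924 or 704 in place of 1548.

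In tas3c1, siRNAs of both C fragments fell in all 3 libraries, and those of A 5′, A 3′ and B fell by smaller amounts. C chain stood at 3.07 ± 0.391 CPM, 23.4-fold below WT (log2 fold change -4.73 ± 0.22, adjusted p = 5.93e-17). C target had no read in tas3c1, at least 34.2-fold below WT (adjusted p = 4.70e-10). CGATCCTTGGAGCAACTCTCC of C chain stood at 54.6 ± 3.28 CPM in WT and 0.549 ± 0.222 in tas3c1. C chain was 96.7% sense in WT, and its in-register share, counted in the commonest WT register, was 93.2% ± 1.38 in WT and 27.9% ± 7.27 in tas3c1 (exact permutation p = 0.1). The tas3c1 share rests on 84 reads, 23 of them in register. Both C fragments were chosen for low reads in tas3c1, and the register was taken from WT. Neither the adjusted p values above nor this share is therefore independent evidence.

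A 5′ stood at 97.9 ± 10.2 CPM in tas3c1 (-0.66 ± 0.15, adjusted p = 0.00132), A 3′ at 40.1 ± 6.92 (-0.62 ± 0.17, adjusted p = 0.00949) and B at 465 ± 62.1 (-0.51 ± 0.15, adjusted p = 0.0176). All 3 libraries lay below WT for the A fragments, and for B the groups overlapped. The median log2 fold change in tas3c1 was -0.40 over the 28 microRNA families and -0.37 over the 24-nt sequences. Much of these 3 falls may therefore be a shift shared with other small RNAs, which was not tested. Calls were lost for A 3′ without WT replicate 1 or tas3c1 replicate 3 (adjusted p = 0.0600 and 0.0589) and for B without WT replicate 3 or tas3c1 replicates 2 or 3 (0.0781, 0.0720 and 0.0820). Both were also lost without TMM (0.0680 and 0.106), so that 3 of the 5 fragments were then called.

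tasiARF fell in tas3c1, to 7.82 ± 1.41 CPM (-0.50 ± 0.20, adjusted p = 0.0203), with 1 library inside the WT range. The 20 to 22 nt reads stood at 28.1 ± 3.28 CPM (-0.46 ± 0.15, adjusted p = 0.00395). miR390 fell to 40.9 ± 6.84 CPM (-0.59 ± 0.14, adjusted p = 1.18e-04). The tasiARF call was lost without WT replicate 2 (-0.45, adjusted p = 0.0805), tas3c1 replicate 2 (-0.45, 0.0762) or tas3c1 replicate 3 (-0.39, 0.113), without TMM (-0.32, 0.133) and in DESeq2 (-0.48, 0.0533).

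In tas3c1 all 7 stress and nutrient families fell: miR399 (-1.17 ± 0.17, from 21.1 ± 1.53 to 10.6 ± 1.66 CPM), miR827 (-0.98 ± 0.16), miR169 (-0.80), miR397 (-0.79), miR408 (-0.66 ± 0.14, from 4561 ± 137 to 3280 ± 372 CPM), miR528 (-0.64) and miR398, which targets superoxide dismutases (-0.42). Of the 28 families 15 fell and 1 rose, with a median log2 fold change of -0.40 over all 28. In the development list miR529 (-1.07), miR319 (-0.92 ± 0.13, from 328 ± 14.8 to 198 ± 20.1 CPM) and miR156, which targets SPL genes (-0.56 ± 0.13, from 888 ± 59.8 to 683 ± 106 CPM), fell. miR172, which targets AP2-like genes, rose (0.57 ± 0.17, from 12.6 ± 3.38 to 21.8 ± 4.62 CPM, adjusted p = 0.00245), and the other 6 did not pass. In the auxin list miR167 (-0.71 ± 0.13, to 632 ± 104 CPM) and miR164 (-0.39) fell, and miR160 stood at 169 ± 22.4 CPM against 141 ± 29.0 in WT. miR168 (-0.41) fell among the 2 machinery families and miR820 (-0.47), which targets a DNA methyltransferase, among the 4 monocot or grass families. All tas3c1 libraries lay below all WT libraries for 14 families and above them for 3, where chance gives 10% for both directions together, and of the mature sequences 17 fell over all sequences and 21 were called when adjusted over the list alone. The increase of miR172 lost its call in DESeq2 (0.62, adjusted p = 0.0663) and without tas3c1 replicate 3 (0.40, adjusted p = 0.102), and the decrease of miR164 lost its call without WT replicate 1 or tas3c1 replicate 3 (adjusted p = 0.0810 and 0.171). Without TMM the calls on miR164, miR168 and miR398 were lost (adjusted p = 0.205, 0.103 and 0.153), miR393 and miR1425 were called higher, and the split was 12 lower and 3 higher.

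Single sequences called in tas3c1 numbered 6350, with 3482 higher and 2868 lower. Of the increases, 1846 encode Cas9 peptides, and of the 2107 increases of 21 to 22 nt 1675 do, or 79.5%. With Cas9 sequences and reads left out, 1400 rose and 2299 fell. Of the 24-nt sequences 1154 fell and 221 rose, and without TMM 559 fell and 469 rose, so the size of this imbalance rests on the scaling. Of the 10 named decreases 8 were 24 nt long, such as GGTTCTGCTTGCTACATCTGCTGC, with 8.15 CPM in WT and no read in tas3c1, at least 74.4-fold lower. That sequence also had 1 read in tas3a1 and none in tas3b1. CGATCCTTGGAGCAACTCTCT, a near copy of the leading C chain siRNA, stood at 4.49 CPM in WT and had no read in tas3c1, at least 41.0-fold lower. Of the 10 named increases, at 25.2 to 38.0 CPM with no WT read, 9 encode Cas9 peptides. Without TMM 5593 rose and 1495 fell, or 78.9% higher in place of 54.8%.

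Differences between mutants were tested for the 5 fragments, tasiARF and miR390, and 14 of the 21 passed. Of these 14, the 4 tests of C chain and C target against tas3c1 concern the property by which these fragments were chosen and are no independent evidence. The A fragments were lower in tas3a1 than in tas3b1 (A 5′ -3.07 ± 0.16, adjusted p = 7.92e-15) and than in tas3c1 (-2.59 ± 0.16, adjusted p = 4.00e-14). B was lower in tas3b1 than in tas3a1 (tas3a1 minus tas3b1, 1.86 ± 0.16, adjusted p = 4.91e-10) and than in tas3c1 (tas3b1 minus tas3c1, -1.46 ± 0.15, adjusted p = 3.87e-09). C chain was lower in tas3c1 than in tas3a1 (tas3a1 minus tas3c1, 4.80 ± 0.22) and than in tas3b1 (tas3b1 minus tas3c1, 4.39 ± 0.21). tasiARF of 21 nt was higher in tas3a1 than in tas3b1 (0.80 ± 0.23, adjusted p = 0.00202), while the 20 to 22 nt reads were lower in tas3a1 (-1.15 ± 0.16, adjusted p = 8.55e-10). tas3b1 minus tas3c1 was -1.09 (adjusted p = 1.60e-05) for 21 nt and -0.24 (0.210) for 20 to 22 nt, and tas3a1 minus tas3c1 was -0.29 (0.230) and -1.39 (8.02e-14), so the order of these mutants depends on which reads count as tasiARF. miR390 differed between tas3a1 and tas3c1 (0.35 ± 0.14, adjusted p = 0.0374), and the tests of tas3a1 against tas3b1 (adjusted p = 0.166) and tas3b1 against tas3c1 (0.465) did not pass.

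Some changes of microRNA families and single sequences were shared by all 3 mutants or by pairs of them. miR164, miR167, miR319, miR397 and miR827 fell in all 3 mutants, 5 families where independent lists of these sizes give 2.95, and of these all but miR397 lost their tas3a1 call in at least 1 alternative fit, as did miR164 in tas3c1 (see above). Single sequences called in all 3 numbered 33 higher, 14 of them 24 nt long, and 25 lower, 17 of them 24 nt long, where independent lists give 0.251 and 0.167. For pairs of mutants, 54 sequences rose and 27 fell in both tas3a1 and tas3b1 (2.55 and 2.05 for independent lists), 45 and 59 in tas3a1 and tas3c1 (12.9 and 6.83), and 194 and 504 in tas3b1 and tas3c1 (67.7 and 70.1). Without TMM only 444 sequences fell in tas3b1 at all, fewer than these 504, so the shared decreases of tas3b1 and tas3c1 rest in part on the scaling. The overlaps of pairs were not computed without TMM. Simulated data without group differences but with shared WT libraries gave at most 1 shared call. Few sequences are called at all in such data, so this number was low by construction and does not measure what shared controls add. The fold changes of the 3 pairs correlated across sequences, which are not independent replicates, with r of 0.492, 0.458 and 0.410, and simulated shared controls alone gave 0.533, 0.531 and 0.539. Their covariances were 0.224, 0.583 and 0.559, above the 0.0547, 0.0548 and 0.0547 that simulated shared controls gave. These values and the overlaps of single sequences cover all 35276 sequences, those that encode Cas9 peptides included. Such sequences were 6, 12 and 1846 of the called increases in tas3a1, tas3b1 and tas3c1. No version without them was computed, so transgene reads may add to these values. How much of the overlap comes from the shared controls was not determined, since 3 WT libraries cannot be divided with 2 or more for each mutant.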

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

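All tests in this part were chosen after the result was seen. Reads of 20 to 24 nt that encode Cas9 peptides, which no comparison was planned on, stood at 262 CPM in WT (highest library 307), 383 in tas3a1, 381 in tas3b1 and 30706 in tas3c1, and all libraries of tas3b1 and tas3c1, and 2 of 3 of tas3a1, lay above the highest WT library. The same protein sequence read backwards gave 195 CPM in WT, 183 in tas3a1 and 203 in tas3b1. The source of the Cas9 reads in WT, tas3a1 and tas3b1 was not tested. Peptides of hygromycin phosphotransferase, a plant selection marker, stood at 66.5 CPM in tas3b1 and 80.9 CPM in tas3c1 against 47.0 in WT and 49.6 in tas3a1, with 22.01 in WT for the same protein sequence read backwards. Reads across a junction in fragment B stood at 23.7 CPM in tas3b1, with 2 reads in WT. Reads of 2 guide RNAs joined to their scaffold stood at 19.4 CPM (guide 1) and 1.498 CPM (guide 2) in tas3c1, with 1 and 0 reads in WT.

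The surplus of 21 to 22 nt sequences in tas3c1 may come from small RNAs of a Cas9 transgene. Cas9 peptides were encoded by 79.5% of the called increases of that length and by 0 of 657 called decreases, and reads covered 98.1% of the protein. The 0 is no contrast. Leaving out Cas9 sequences took the table from 35276 to 33427 sequences, and 1846 Cas9 sequences were called increases, so almost none could have been decreases. The share that Cas9 reads take of each library was examined as a cause of the other calls. Of the 4504 called sequences in which no Cas9 peptide was found, 3699 (82.1%) stayed called in the same direction without Cas9 sequences and reads. Both fits used TMM scaling, which already allows for such a share, so this test could hardly have come out otherwise and decides little. These 3699 can still hold transgene reads, since the shortest reads were searched in only some frames and other parts of a transgene were not removed. The reverse complement of the last 14 bases of guide 2 before its scaffold occurs in C target (the rest was not compared), and the reverse complement of guide 1 begins with 10 of 10 bases from the end of the miR390 complement. Whether the transgene itself or the mutation changed the remaining sequences stays open, since all 3 tas3c1 libraries share the mutation and the Cas9 reads.

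The loss of phased siRNAs from fragment B in tas3b1 may reflect a deletion that ends in the 3′ miR390 site. A lower output of the whole locus with unchanged phasing is argued against, since reads outside the register stood at 120% of WT while those in it stood at 3.50%. These percents cannot show whether output also fell, because siRNAs that lose the register are counted as outside it. Up to position 197 the 21-nt reads of B stood at 443 CPM in WT and 170 in tas3b1. Junction reads numbered 677 in tas3b1, 2 in WT, 0 in tas3a1 and 1 in tas3c1, and a stretch of the unbroken sequence across the upstream side of the break had 0 reads in tas3b1 and 31 in WT, although 21-nt reads that cross or lie past the break still stood at 0.145 CPM in tas3b1 (138 in WT). The bases after the break equal the 3′ end of the miR390 complement at 7 of 7 positions. The genomic sequence was not measured, so a deletion remains a hypothesis.

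The sequences changed the same way in all 3 mutants, 33 higher and 25 lower, could arise from the shared WT libraries or from a difference in origin between WT and mutant plants. Chance differences of the WT libraries were not decided: a first test on simulated data without group differences, replaced after its outcome was seen, gave at most 0 such sequences, which excludes nothing, and the WT libraries stood apart from the other 9 for 1189 sequences, a number first set against 216 sets of 3 libraries not all of 1 group (at most 1973, median 197; over 4-fold 46 for WT and at most 55). Sets with 2 libraries of 1 group carry that group's own differences. After this outcome the test was therefore limited to the 108 sets from 3 groups. These gave at most 830 (median 143.5, over 4-fold at most 9) but are kept low by group differences. Libraries without any structure would give 304 on average. The highest set from 3 groups exceeds that average and their median lies below it, so none of these is a firm chance level. TMM scaling is argued against, since 56 of the 58 sequences stayed called the same way in all 3 mutants without TMM, a test that replaced one on their smallest log2 fold change (0.473 in size), which the threshold for a call bounds. A difference in origin of the plants cannot be told apart from the mutations, because WT is a single group, so its 33 shared increases decide nothing.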

How the results depend on the processing

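The tests without Cas9 sequences and the alternatives for differences between mutants were chosen after the results were seen. Over the alternatives fixed in advance, 149 of 177 values for the comparisons kept their direction and side of the threshold, or their size. The cause of the changes below was not tested unless stated.
Counting distinct sequences in place of reads turned the difference in the 21-nt share to 0.211 points in tas3a1 and 0.198 in tas3b1. A minimum of 0.5 CPM, which tests more sequences, called 654 sequences in tas3a1 and 11996 in tas3c1. Without Cas9 sequences 3699 were called in tas3c1. Without TMM 1 fragment was called in tas3b1 and 3 in tas3c1, 12 families in tas3b1, and tasiARF in tas3c1 changed by -0.32. DESeq2 gave -0.48 for the latter. Reads that hold nucleotides 3 to 18 gave 4 families in tas3a1.
Leaving out each replicate gave 104 (without WT replicate 1) to 228 called sequences in tas3a1, 704 (without tas3b1 replicate 2) to 1447 in tas3b1 and 4264 to 5842 in tas3c1. It gave 1 fragment in each fit for tas3b1, 3 (without tas3c1 replicate 3) to 5 for tas3c1, and 4 (without tas3a1 replicate 3) to 7 families in tas3a1, 18 to 22 in tas3b1 and 14 to 20 in tas3c1. tasiARF ranged from -1.02 to -0.59 in tas3a1, -1.65 to -1.54 in tas3b1 and -0.67 to -0.39 in tas3c1. The tasiARF call was lost without tas3a1 replicate 3 in tas3a1, and without WT replicate 2, tas3c1 replicate 2 or tas3c1 replicate 3 in tas3c1. Counts were also over 1.5 times lower without WT replicate 2 in tas3a1 (139) and without WT replicates 1, 2 or 3 in tas3b1 (1009, 808 and 924).
Among families and fragments that did not pass the test, some signs turned, and none of these values is a call. When replicates were left out, tas3a1 values ranged from -0.15 to 0.20 for C chain, -0.24 to 0.078 for miR159, -0.28 to 0.0017 for miR166, -0.021 to 0.20 for miR172, -0.11 to 0.026 for miR394, -0.39 to 0.16 for miR529 and -0.062 to 0.091 for miR1425. They ranged from -0.094 to 0.13 for miR398 and -0.27 to 0.017 for miR528 in tas3b1, and from -0.036 to 0.19 for miR160, -0.019 to 0.20 for miR171 and -0.027 to 0.29 for miR535 in tas3c1. Without TMM the signs turned for A 5′ (0.024), miR408 (0.00051) and miR528 (0.015) in tas3b1 and miR396 (0.078) in tas3c1, and with nucleotides 3 to 18 for miR394 in tas3a1 (0.026) and miR160 in tas3c1 (-0.052). Over all named items, whether or not they passed, the alternatives fixed in advance gave 1714 values, of which 64 lost and 15 gained a call.
Replicate numbers were not taken to pair the samples: after group means were removed, libraries of WT and a mutant with the same number correlated at -0.155 to 0.0486, those of any 2 groups at up to 0.262 (different numbers up to 0.174), and 5 of 12 libraries were closest to their own number. With the replicate block 291, 1884 and 6869 sequences, 2, 2 and 5 fragments, 7, 22 and 16 families, tasiARF changes of -0.78, -1.57 and -0.49 and 14 differences between mutants were found.
Not run, for want of a rice genome, were the alternatives for small RNA loci, reads with up to 20 genome places and genome-matched reads as denominator. Depth limits rare siRNAs: 3 reads over a group equal 0.106 to 0.119 CPM.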

Other observations

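The tests on other splits of the libraries were chosen after the results were seen. Families that mark reproductive phased siRNAs were near 0 in these shoots: miR2118 stood at 0.399 ± 0.186 CPM in WT with 11 reads, and miR2275 had 1 read. miR395, which answers sulfate supply, had no read in WT, and miR530 had none in any group. The families with the highest WT levels were miR396 (8548 ± 626 CPM), miR408 (4561 ± 137), miR166 (1715 ± 445), miR167 (910 ± 96.5) and miR156 (888 ± 59.8). Among named 24-nt sequences some were scarce in all 3 mutants, such as ATCCGTGAAACGTACGATCTATGC (3.04 CPM in WT, no read in any mutant). Others were scarce in WT alone, such as AATCGGACCGTAGATTAGATGAGT, with 0.1004 CPM in WT and 4.02, 3.61 and 4.35 CPM in tas3a1, tas3b1 and tas3c1.

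For each comparison the 6 libraries make 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as large a count for sequences, fragments and families alike. The real splits called 215, 1548 and 6350 sequences in tas3a1, tas3b1 and tas3c1, with 86, 0 and 0 in the highest other split. They called 2, 2 and 5 fragments and 7, 22 and 16 families, with 0 in the highest other split. The other splits mix WT and mutant libraries, so any group difference widens their spread and lowers their counts. C chain and C target were chosen for low reads in tas3c1, so their calls there are no independent evidence.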
